A study of Nymphaea colorata with 9 samples.

How the data were processed

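Poly(A) RNA from outer tepals, inner tepals and stamens of stage 3 floral buds of Nymphaea colorata was sequenced as paired reads of 150 bases from TruSeq libraries, per the labels' protocols. Each organ had 3 libraries, and organ and replicate number were taken from the sample titles. The submitters' processing notes name fastp, HISAT2 and StringTie. Versions of fastp and HISAT2, trimming and alignment settings, and a genome build name are not given in the sources used here. StringTie 2.2.1 was run for each library on reference transcripts alone, per the file headers, so that no transcript outside the annotation was quantified. Gene IDs, coordinates and exons are those of the annotation in the deposited files, whose records name Phytozome as their source. Coordinates count from 1 on that assembly. The letters A to N in gene IDs stand for 14 single sequences, and the letter O for 328 sequences that hold 1878 genes.

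The deposited gene tables held 3 measures for 24059 genes. Coverage, a signal in mean read depth per base, was written by StringTie without normalization, per the file headers. FPKM was deposited beside it, and the values show that it is coverage divided by all aligned bases of the library. TPM as deposited by the authors has the same sum in each library and was used for the results. The deposited transcript files held coverage, FPKM and TPM for 43975 transcripts, with exons. These are not counts, so no count model was fitted. The aligned bases of each library were recovered from the ratio of coverage to FPKM. They ranged from 5.08 to 6.21 Gb, of which 89.1 to 91.1% lay in annotated genes, and correspond to 33.9 to 41.4 M reads of 150 bases. Reads are such equivalents throughout, and they were not counted molecules. A transcript of 1896 bases needed 0.0749 to 0.0906 TPM to reach 3 reads. These limits cover counting error only, since reads copied by PCR are not independent molecules. The mates of a pair are counted here as separate reads though they come from the same fragment, so fewer fragments stand behind each value. Between 15924 and 17038 genes per library reached 1 TPM, and 1947 genes were listed at 0 in all 9 libraries.

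Genes at 1 TPM or more in at least 3 of the 9 libraries, 17604 in all, were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. One linear model with the 3 organ means was fitted to all 9 libraries, with moderated variances that followed a trend on abundance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, separately in each of the 3 comparisons between organs. Log2 differences are on the log2(TPM + 1) scale, which understates the change of genes at low levels. The tests are two-sided. The median standard error of a log2 difference was 0.33, and 0.21 with the replicate block. Nothing in the labels says that the libraries of an organ came from separate plants or buds, so p-values measure the spread between these libraries, which may be technical in part.

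Genes higher or lower in an organ than in both others were those called in the same direction in both comparisons. Because such comparisons share libraries, the overlap was set beside 100 simulated draws with no effect and beside the overlap of independent lists of the same sizes. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. No pair of libraries held identical values, and the highest correlation of log2 values was between outer tepal replicates 1 and 2 at 0.935.

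The labels give the same numbers 1 to 3 to the libraries of each organ and do not say what a number marks. The data show that the numbers pair the libraries. Deviations from the organ means, correlated across genes, had a mean r of 0.568 (0.259 to 0.720) in the 9 pairs of libraries with the same number. All 9 libraries were closest to a library of their own number. Pairs with different numbers are not set beside these, since deviations sum to 0 within each organ and this fixes their mean. A fit with the number as a block was therefore run beside the planned fit without it, and its values are given where they change a count by over 1.5 times.

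The tests of the comparisons, of genes set apart in stamens and of the inner tepal position were fixed before the data were examined. So were the filter, 23 gene lists, the rule for naming genes and most alternatives. The lists were written for floral organ identity, pollen and anther development, pigment, photosynthesis, cell division, hormones, vascular and carpel tissue, stress and similar themes, to be matched on gene names or product descriptions. None of the gene IDs has a name in the tables, and 0 matched the RefSeq name table of assembly ASM883128v2. No list could be tested, no marker of another tissue could be looked up, and no gene is given a function. Without names, the rule names in each comparison at most 2 genes in each direction. These are the called genes with the largest absolute log2 difference among those with a mean of at least 10 TPM in the higher organ and no overlap between the organs. Its condition on product descriptions could not apply.

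The procedure was tested on simulated data made from the libraries' means and spreads. For stamen against outer tepal, with 200 of 17604 genes changed in each of 10 runs, 40.2% of genes changed by a log2 difference of 1.5 and 89.4% of those changed by 3 were recovered, with a mean of 6.3 false calls. The changed genes were drawn from the more abundant tested genes alone, so recovery at lower levels was not measured. In the data 27.5% of tested genes were called in that comparison, and the simulated libraries were not paired by number. Recovery and false calls in the data may therefore differ from these values. Alternatives covered the pseudocount, the filter on low TPM, FPKM, median-of-ratios scaling, quantile normalization, limma voom on read equivalents, the 6 libraries of a comparison alone, no trend, the replicate block and each library left out in turn. Genes whose reads could be shared with a near-identical copy or an overlapping gene were not identified here, since no genome sequence was used, so the level of a single gene may include reads of a copy. Whether alignments used strand is not given in the sources used here.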

Results

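RNA was measured in 3 floral organs of Nymphaea colorata, a water lily with blue flowers that belongs to one of the earliest-diverging lineages of flowering plants. The organs were the outer tepals, the inner tepals and the stamens of floral buds that the labels place at stage 3. Tepals are the leaf-like organs around the reproductive parts of the flower, and stamens are the organs that make pollen. Each organ was represented by 3 libraries, numbered 1 to 3, which gives 9 libraries of poly(A) RNA. The values were transcript abundances (TPM, scaled to the same sum in each library) for 24059 genes. The depth that the deposited coverage implies was 5.08 to 6.21 Gb of aligned bases per library, or 33.9 to 41.4 M reads of 150 bases. At this depth a gene at 1 TPM with the median transcript length of 1896 bases rested on 33.1 reads in the library of lowest depth. Counting error alone was 15.8 to 17.4% of its value if every read is independent. The mates of a pair come from the same fragment, so the error is larger. A total of 17604 genes reached 1 TPM in at least 3 libraries and were tested. The deposited tables pair no gene ID with a gene name, so genes are given by ID, and the letter in an ID names the genome sequence on which the gene lies.

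The organs separated over the whole transcriptome. The first principal component of log2(TPM + 1) held 48.2% of the variance and placed the outer tepals at one end, the stamens at the other and the inner tepals between them. The second component held 22.995%, and within each replicate number the inner tepal lay lowest on it. For numbers 1, 2 and 3 the inner tepals stood at -16.0, -72.8 and -79.5. The outer tepals stood at 74.9, 30.8 and -10.2 and the stamens at 80.4, -19.3 and 11.8. Position on the axis from the outer tepal mean, set to 0, to the stamen mean, set to 1, was 0.389 ± 0.0423 (SD, n = 3) for the inner tepals. Such a position takes no account of differences off that axis. The outer tepal libraries, each left out of its own axis, lay at 0.0833 ± 0.133 (SD, n = 3), and the stamen libraries at 0.893 ± 0.124 (SD, n = 3). Each inner tepal library, at 0.348 to 0.433, lay above all outer tepal libraries and below all stamen libraries. The two-sided exact permutation test gave p = 0.1 for inner against outer tepal and p = 0.1 for stamen against inner tepal, the smallest value that 3 libraries against 3 allow. The axis was built from the organ labels and was not rebuilt in the permutations. Only outer tepal and stamen libraries were left out of it in turn. These p-values therefore give no more than the order of the positions on that axis.

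**Figure D1:**
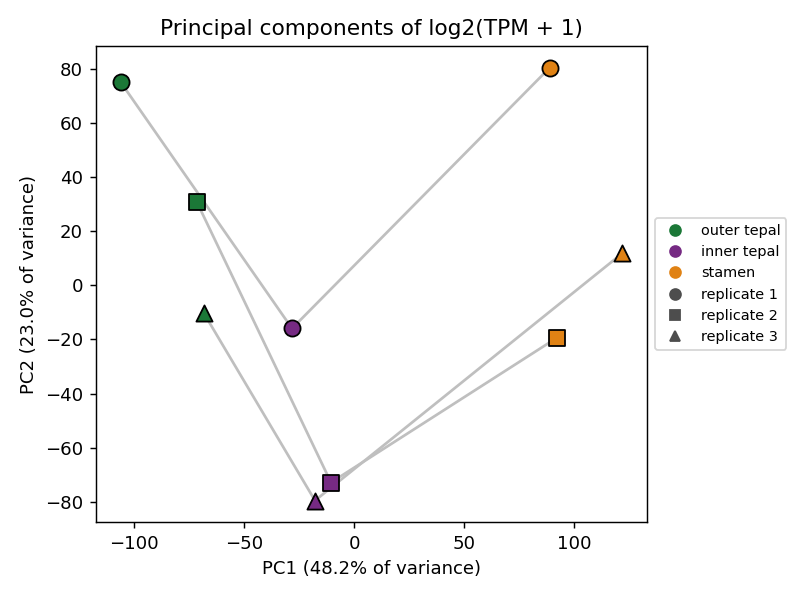
Principal components of log2(TPM + 1) over the 17604 tested genes, with the first component (48.2% of variance) on the x axis and the second (22.995%) on the y axis. Each point is a library, colours mark organs, shapes mark replicate numbers, and grey lines join libraries with the same number; the inner tepals lie between the outer tepals and the stamens along the x axis.

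**Figure D2:**
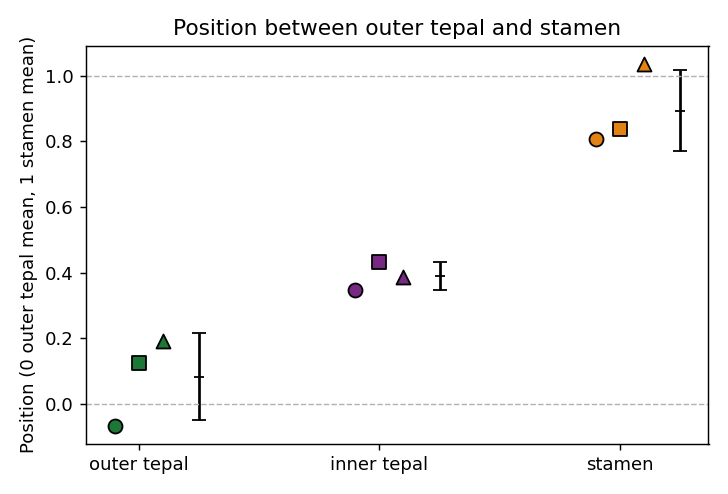
Position of each of the 9 libraries on the axis from the outer tepal mean (0) to the stamen mean (1), with points for libraries, shapes for replicate numbers, and the mean and SD of each organ as a bar beside the points. The inner tepal libraries lie at 0.348 to 0.433, above all outer tepal libraries and below all stamen libraries.

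The comparison of inner with outer tepals sets the outer against the inner perianth organ at one stage. The inner tepals differed from the outer tepals mainly by genes at lower levels. Of 517 genes that passed the limma test, 463 were lower in the inner tepals and 54 were higher, so that 89.6% of the called genes were lower. The median log2 difference was -2.54 for the lower genes and 1.97 for the higher genes, and 165 of the lower genes differed by at least 8-fold. With the replicate number as a block, 2028 genes passed, 1515 lower and 513 higher, and these held all 517 of the genes called without the block.

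Nycol.K01201.v1.2, a gene with a single exon on sequence K at 16289485 to 16290288, plus strand, was among the most abundant genes of the outer tepals. It stood at 8817 ± 4321 TPM (SD, n = 3) in outer tepals and at 54.3 ± 38.2 TPM (SD, n = 3) in inner tepals, a log2 difference of -7.49 with a standard error of 0.54 (limma, adjusted p = 0.000394). Nycol.G00706.v1.2, with 3 exons on sequence G at 15480960 to 15483904, plus strand, fell from 317 ± 237 to 0.405 ± 0.140 TPM (SD, n = 3 each; log2 difference -7.58, standard error 0.46, limma adjusted p = 0.000221). In the other direction, Nycol.A03014.v1.2 stood at 90.3 ± 16.3 TPM in inner and 2.58 ± 0.276 TPM in outer tepals (SD, n = 3 each; log2 difference 4.66, standard error 0.24, limma adjusted p = 0.000221). It has 9 exons and 2 transcripts on sequence A at 37558202 to 37573999, minus strand. Its stamen libraries held 213, 341 and 212 TPM. Nycol.H00347.v1.2, with 5 exons on sequence H at 8038979 to 8045093, plus strand, stood at 88.8 ± 62.5 TPM in inner and 2.85 ± 2.60 TPM in outer tepals (SD, n = 3 each; log2 difference 4.55, standard error 0.63, limma adjusted p = 0.00866). Without outer tepal replicate 2 its adjusted p was 0.0504, past the threshold of 0.05, and over all of its alternatives the adjusted p lay between 0.00288 and 0.0504.

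The number of genes called between the tepals moved with single libraries. It was 88 without outer tepal replicate 2, 137 without outer tepal replicate 1 and 678 without outer tepal replicate 3. Without inner tepal replicates 1, 2 and 3 it was 257, 200 and 179. An organ left with 2 libraries has less power, so the falls do not show that the count rests on a single library.

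Genes lower in the inner tepals were mostly lower in the stamens as well. Of the 463 genes, 405 were also lower in stamens than in outer tepals, 58 were not called there and 0 were higher. Under the replicate block the share fell from 87.5% to 72.1%, with 1093 of 1515 genes lower in stamens, 399 not called and 23 higher. Independent lists of the sizes without the block would share 46.2 genes, and those with the block 212. Unchanged groups simulated against shared outer tepal libraries shared 0, but they called at most 2 genes in any comparison, so that value says little about longer lists. These 405 genes took 6.05 ± 0.911% of all TPM in outer tepals, 0.624 ± 0.0918% in inner tepals and 0.366 ± 0.0490% in stamens (SD, n = 3 each), on the libraries by which they were chosen. The 405 became 114, 79 and 478 without outer tepal replicates 1, 2 and 3. They became 213, 168 and 154 without inner tepal replicates 1, 2 and 3. Of the 54 genes higher in inner tepals, 20 were also higher in stamens than in outer tepals, 30 were not called there and 4 were lower. Independent lists would share 9.47 genes higher in both. Under the block the 20 became 145, where independent lists would share 103, and they became 11 with voom and 12 with a pseudocount of 5. Without outer tepal replicates 1, 2 and 3 the count was 5, 3 and 29, and without inner tepal replicates 1, 2 and 3 it was 8, 8 and 6. Across genes, the covariance of the inner tepal and stamen log2 differences from outer tepal was 0.755, against 0.103 in unchanged groups that shared the same outer tepal libraries. The correlation across genes, which are not independent replicates, was 0.603, against 0.501 in those unchanged groups. Those groups hold no organ effects, so genes that set only the outer tepals apart raise these values too. The step from outer to inner tepal and the step from inner tepal to stamen had a covariance of -0.0730, against -0.103 in unchanged groups. Beyond the shared inner tepal libraries, the steps thus showed little common direction across genes. With 3 outer tepal libraries the controls could not be split, so part of the overlap may come from those shared libraries.

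Few genes were particular to the inner tepals without the block. A set of 24 genes was higher in inner tepals than in both other organs and 40 were lower than in both, where independent lists would share 2.82 and 53.0. Under the replicate block these counts were 233 and 247, where independent lists would share 46.8 and 227. With each library left out in turn they ranged from 4 to 53 and from 6 to 87, lowest without outer tepal replicate 2 and highest without outer tepal replicate 3, and after quantile normalization they were 31 and 23. Stepwise change inwards, lower in inner than in outer tepals and lower again in stamens than in inner tepals, was called for 59 genes, where independent lists would share 24.2, and for 165 under the block, where they would share 138. The 59 became 100 after median-of-ratios scaling and 21 without outer tepal replicate 2. Stepwise change in the other direction, higher at both steps, was called for 5 genes, where independent lists would share 6.18, and for 29 under the block, where they would share 77.02. With each library left out in turn the 5 ranged from 1 to 4. Both comparisons behind these counts share the inner tepal libraries, whose errors enter with opposite sign. In unchanged groups their log2 differences had a correlation of -0.500 across genes. Independent lists are therefore too low a baseline for genes particular to inner tepals and too high for stepwise change. One inner tepal library, replicate 1, held stamen genes at a low level. Of 87 genes at 5 TPM or more in all stamen libraries and under 1 TPM in the other 5 tepal libraries, 48 reached 1 TPM in inner tepal replicate 1, at a median of 5.85% of their level in stamen replicate 1.

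**Figure D3:**
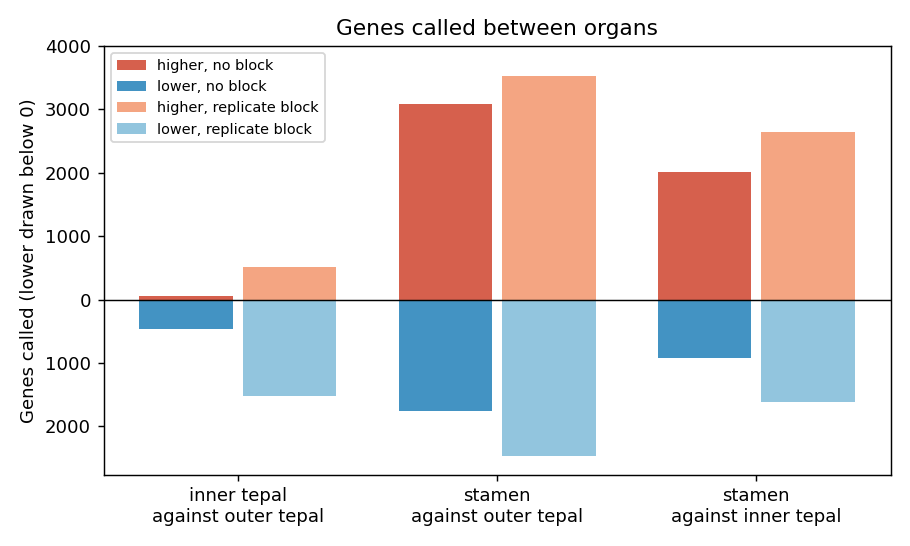
Number of genes called by limma in each of the 3 comparisons between organs, with genes higher in the first-named organ above 0 and lower genes drawn below 0; dark bars are without and light bars with the replicate number as a block. Between the tepals 463 of 517 called genes were lower in the inner tepals, and the block raised the count to 2028.

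The comparison of stamens with outer tepals sets the pollen-bearing organ against the outermost perianth organ. It gave the largest number of called genes of the 3 comparisons, 4845 or 27.5% of those tested. Of these, 3088 were higher in stamens, with a median log2 difference of 1.53, and 1757 were lower, with a median of -1.95. A difference of at least 8-fold was found for 364 of the higher and 371 of the lower genes.

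Nycol.B00079.v1.2, with 4 exons on sequence B at 758331 to 760686, minus strand, stood at 2306 ± 1148 TPM in stamens and 1.65 ± 1.88 TPM in outer tepals (SD, n = 3 each). Its log2 difference was 9.89 with a standard error of 0.91 (limma, adjusted p = 0.000240). Nycol.B02503.v1.2, with 2 exons on the same sequence at 30974776 to 30976322, minus strand, stood at 3603 ± 3130 TPM in stamens and 2.35 ± 2.01 TPM in outer tepals (SD, n = 3 each; log2 difference 9.29, standard error 1.96, limma adjusted p = 0.00784). Its stamen libraries ranged from 202 to 6361 TPM. Among lower genes, Nycol.K01201.v1.2 was listed at 0 in all 3 stamen libraries, against 5621, 7097 and 13734 TPM in the outer tepals, and no fold is given for it. Nycol.G00707.v1.2, a single-exon gene on sequence G at 15488009 to 15489040, plus strand, stood at 0.356 ± 0.486 TPM in stamens and 813 ± 431 TPM in outer tepals (SD, n = 3 each; log2 difference -9.16, standard error 0.47, limma adjusted p = 3.96e-05).

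The balance of higher and lower genes depended on the scale. On TPM as deposited the median log2 difference of all tested genes between stamens and outer tepals was 0.34, and 63.7% of the called genes were higher in stamens. After median-of-ratios scaling, which sets that median to 0.00, 4178 genes were called, 1799 higher and 2379 lower, so that 43.1% were higher. After quantile normalization, 4440 were called, 2303 higher and 2137 lower. Of the 4845 genes called on TPM, 3554 kept their call and direction under median-of-ratios scaling and 4035 under quantile normalization.

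The comparison of stamens with inner tepals sets the stamen against the perianth organ next to it. Fewer genes were called, 2933 or 16.7% of those tested, and 2014 of them were higher in stamens. The median log2 difference was 1.68 for the 2014 higher genes and -1.85 for the 919 lower genes. With the replicate number as a block 4250 genes were called, 2643 higher and 1607 lower. At least 8-fold differences were found for 266 higher and 93 lower genes. Nycol.B00079.v1.2 was again among the genes with the largest difference, at 2306 ± 1148 TPM in stamens and 7.12 ± 10.7 TPM in inner tepals (SD, n = 3 each; log2 difference 8.98, standard error 0.91, limma adjusted p = 0.000779). Its inner tepal libraries held 19.5, 0.830 and 1.02 TPM. Nycol.I01824.v1.2, with 4 exons on sequence I at 24163917 to 24165777, plus strand, stood at 121 ± 55.3 TPM in stamens and 0.226 ± 0.204 TPM in inner tepals (SD, n = 3 each; log2 difference 6.53, standard error 0.38, limma adjusted p = 0.000208).

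Nycol.K00691.v1.2 was the most abundant of the named genes and stood high in both kinds of tepal. It has 2 exons on sequence K at 9863501 to 9864738, minus strand. It stood at 11733 ± 4331 TPM in inner tepals and 226 ± 198 TPM in stamens (SD, n = 3 each; log2 difference -6.22, standard error 0.86, limma adjusted p = 0.00253). The outer tepal libraries held 12708, 14078 and 12592 TPM of it. Nycol.K01201.v1.2, listed at 0 in the stamens, held 94.3, 18.3 and 50.2 TPM in the inner tepals.

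Here too the balance moved with the scale. The median log2 difference of all tested genes between stamens and inner tepals was 0.19 on TPM and 0.01 after median-of-ratios scaling, and the share of called genes that were higher in stamens was 68.7% and 54.0%. Quantile normalization gave 50.8%. Of the 2933 genes, 2422 kept their call and direction under median-of-ratios scaling and 2328 under quantile normalization. The count was 1637 without inner tepal replicate 1, the library that held stamen genes at a low level, 1833 without stamen replicate 1 and 1658 without stamen replicate 3.

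**Figure D4:**
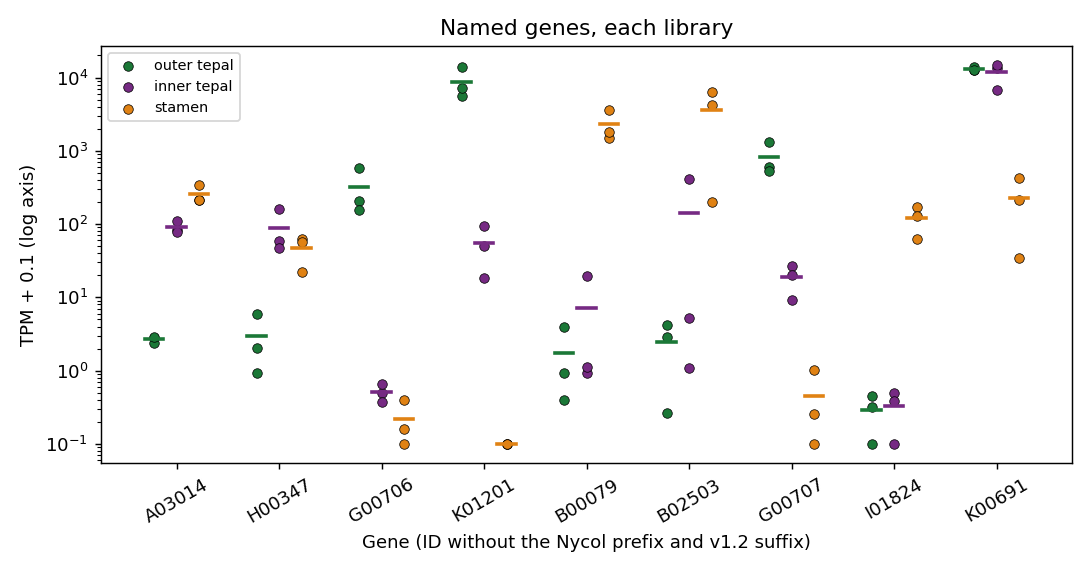
TPM plus 0.1 on a log axis for the 9 named genes in each of the 9 libraries, with a point for each library, a line for each organ mean and colours for organs. Nycol.K01201.v1.2 is listed at 0 in all 3 stamen libraries and stands at 5621 to 13734 TPM in the outer tepals.

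Genes that set stamens apart from both kinds of tepal were called in both directions. A total of 1727 genes were higher in stamens than in both tepals, and 588 were lower than in both. Independent lists would share 353 and 91.7 genes. Unchanged groups simulated against shared stamen libraries shared at most 0 and 1, a value that says little, since they called at most 2 genes in any comparison. The 1727 genes took 14.7 ± 2.62% of all TPM in stamens, 4.09 ± 0.484% in inner tepals and 3.62 ± 0.753% in outer tepals (SD, n = 3 each). The 588 genes took 1.91 ± 0.508% in stamens, 12.8 ± 1.96% in inner tepals and 18.5 ± 1.69% in outer tepals (SD, n = 3 each). Both sets of shares were measured on the libraries by which the genes were chosen. With 3 stamen libraries the shared group could not be split, so part of the overlap may come from it. Under the replicate block the lower set held 998 genes, where independent lists would share 225. It held 901 genes after median-of-ratios scaling and 911 after quantile normalization. The higher set held 926 genes without stamen replicate 3, 1024 without inner tepal replicate 1 and 1135 without stamen replicate 1, and the lower set held 348 without inner tepal replicate 1.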

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

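The alternatives for genes higher or lower in outer or inner tepals than in both other organs, for genes that fall or rise at both steps, for genes at 5 TPM or more in 1 organ and under 1 TPM elsewhere and for the share of the most abundant genes were chosen after the data were seen, and the other alternatives before. Each of the 12 named genes and comparisons kept its direction in all 240 alternatives run, and 239 kept the call. The exception was Nycol.H00347.v1.2 without outer tepal replicate 2. Without an outer tepal library Nycol.G00706.v1.2, and without a stamen library Nycol.I01824.v1.2, no longer passed the filter, so these 6 fits were run on the genes that pass with all 9 libraries, a choice made after the data were seen. The balance of calls between stamens and outer tepals turned from 63.7% higher in stamens to 43.1% after median-of-ratios scaling. With the replicate number as a block, which takes the pairing into account, genes called between the tepals rose from 517 to 2028 and genes lower in stamens than in both tepals from 588 to 998. The block changed no call of a named gene and moved no other planned total by over 1.5 times. Within the total for stamens against inner tepals, the lower genes went from 919 to 1607. The 588 became 901 after median-of-ratios scaling and 911 after quantile normalization, and the cause of these shifts was not tested. Genes called between the tepals, between stamens and outer tepals, and between stamens and inner tepals stayed within 1.5 times of their counts under the other alternatives that keep all libraries of the compared organs. Voom on read equivalents gave 357, 4734 and 2813.

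Leaving out each library in turn gave 88 to 678 genes between the tepals, 3449 to 4758 between stamens and outer tepals, and 1637 to 2950 between stamens and inner tepals. An organ left with 2 libraries gives less power by construction, but the 678 without outer tepal replicate 3 lay above the 517 of all libraries, and its cause was not tested. Genes higher in stamens than in both tepals numbered 926 to 1649, and genes lower than in both 348 to 595. Genes higher in outer tepals than in both other organs numbered 79 to 478, genes lower than in both 3 to 29, and genes that fall at both steps 21 to 66. The inner tepal position lay between 0.331 without outer tepal replicate 1 and 0.447 without outer tepal replicate 3. Genes at 5 TPM or more in 1 organ and under 1 TPM elsewhere numbered 18 to 40 for outer tepals, 0 to 1 for inner tepals and 39 to 87 for stamens. At 1 TPM against under 0.1 they numbered 9, 0 and 14, and at 10 TPM against under 1 they numbered 8, 0 and 13.

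The gene list tests and their alternatives were not run, because no gene ID was matched to a name. Depth limits genes near 1 TPM, where counting error alone is at least 15.8 to 17.4%, since the mates of a pair are not independent. Values under 0.0749 to 0.0906 TPM rest on fewer than 3 reads for a transcript of 1896 bases.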

Other observations

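The counts of genes at 5 TPM or more in 1 organ and under 1 TPM elsewhere, the share of the most abundant genes, the tests on stamen genes in inner tepal replicate 1, those on neighbours among genes lower in stamens and higher in outer tepals, those on neighbours that point away from each other, the splits within replicate numbers and the splits of transcript shares were chosen after the results were seen. The tests on libraries with the same number were set before they were run, but after the pairing itself was known. Those on gene structure and on transcript shares were not among the tests fixed before the data were examined.

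Stamens and outer tepals each had genes that stood low in all libraries of the other organs, and inner tepals had none by the same rule. At 5 TPM or more in all 3 libraries of an organ and under 1 TPM in the other 6, there were 39 genes for stamens, 18 for outer tepals and 0 for inner tepals. Levels under 1 TPM can still rest on reads, and at 1 TPM or more against under 0.1 TPM elsewhere the numbers were 14, 9 and 0. At 5 TPM against under 1 TPM, the highest number for any of the 81 other sets of 3 libraries was 11. The stamen number was 87 without inner tepal replicate 1 and 78 without stamen replicate 2, and the outer tepal number was 40 without outer tepal replicate 3. The most abundant genes took a smaller share of TPM in stamens. The 10 most abundant genes took 4.93 ± 0.963% of TPM in stamens (SD, n = 3) and 8.41 ± 1.07% in tepals (SD, n = 6), a two-sided exact permutation p of 0.0119, the smallest that these 9 libraries allow. The difference lay between -3.99 and -3.03 percentage points with each library left out in turn. The share was lowest in the stamen for each of the 3 replicate numbers. For the 100 most abundant genes the shares were 15.2 ± 1.09% and 21.7 ± 1.40% (SD, n = 3 and 6, exact permutation p = 0.0119). The number of genes at 1 TPM or more was 16815 ± 298 in stamens and 16391 ± 354 in tepals (SD, n = 3 and 6, exact permutation p = 0.119). These were 3 measures of the same family, with unadjusted p. The permutations took no account of the pairing of libraries by number, so these p-values may be too small.

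Called genes differed in structure from random lists of like abundance, and the sets were not tested against one another. Of the 1727 genes higher in stamens than in both tepals, 10.4% had a single exon, against a mean of 17.1% in 2000 random gene lists matched on abundance (14.4 to 19.7%, permutation p = 0.001, the smallest these lists can give). Of the 405 genes higher in outer tepals than in both other organs, 27.7% had a single exon, against 18.7% in matched lists (12.8 to 24.7%, permutation p = 0.001). For the 588 genes lower in stamens it was 14.8%, against 10.4% (permutation p = 0.003). Transcripts were shorter than in matched lists in all 3 sets. The median transcript length of the 1727 genes was 1702 bases, against 1785 (permutation p = 0.001). That of the 405 genes was 1448 bases, against 1755 in matched lists (permutation p = 0.001). For the 588 genes it was 1705 bases, against 1918 (permutation p = 0.001). The median exon number was 5 for the 1727 genes, against 4 in matched lists, and 4 for the 588 genes, against 5.18 (permutation p = 0.001 each). For the 405 genes it was 3, against 3.88, which was not set apart from matched lists (permutation p = 0.2). These p-values are over genes, which are not independent replicates. Few genes were called for a shift in transcript use. Among 4699 genes with a mean of at least 5 TPM in each organ and at least 2 expressed transcripts, limma on the log2 ratio of each transcript to the rest of its gene called a shift of at least 20 percentage points in 1 gene between the tepals, 12 between stamens and outer tepals and 8 between stamens and inner tepals, and in 0, 2 and 0 with the replicate block. At an unadjusted p under 0.05 there were 848, 1255 and 1282 of 14990 transcripts, or 5.66, 8.37 and 8.55%, and 996, 1421 and 1455 with the block, or 6.64, 9.48 and 9.71%. On simulated data for stamen against outer tepal, 33.6% of shares changed by a log2 difference of 2.5 and 90.8% of those changed by 5 were recovered, so smaller shifts can be missed. The changed transcripts were drawn from those near an even share of their gene, so recovery for minor or dominant transcripts was not measured.

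Neighbouring genes were called together more often than at shuffled positions. Neighbours were taken among the tested genes, so untested genes may lie between them. Genes higher in stamens than in both tepals formed 253 adjacent pairs against 169 in the mean of 2000 shuffles (permutation p = 5e-04, the smallest the shuffles can give), a ratio of 1.501. Read-through past the end of a gene does not reach a neighbour that points away from it without overlap, but such pairs had a ratio of 1.68 (67 pairs, permutation p = 5e-04). Reads shared between copies of like structure would leave neighbours unlike in exon number and length without an excess, but the ratio of unlike neighbours was 1.48. Neither read-through alone nor copies of like structure alone thus accounts for the whole excess. Both acting together were not tested, since no class of neighbours was unlike in structure and also pointed away from each other. Copies annotated with unlike structure can still share reads, which these values do not test. For genes lower in stamens the ratio was 2.73, with 2.39 for unlike neighbours and 1.95 for those that point away from each other. These values go against copies of like structure and against read-through, each as the whole cause, the latter narrowly (9 pairs, permutation p = 0.04). For genes higher in outer tepals the ratio was 4.08, and 1.77 among pairs that point away from each other, from 4 pairs, and 1.23 among unlike neighbours, from 8 pairs, keep both explanations open. On the same strand the ratios of these sets in turn were 1.56, 4.09 and 6.34 (permutation p = 5e-04 each). On opposite strands they were 1.44, 1.28 and 1.75 (permutation p = 5e-04, 0.2 and 0.1), so that the last 2 sets showed no excess beyond the shuffles there. Among neighbours both on opposite strands and unlike in structure they were 1.36, 1.65 and 0.609 (permutation p = 0.004, 0.07 and 0.8). These values decide nothing on read-through, since it is not known whether reads were assigned by strand. Shared regulation of neighbouring genes is a hypothesis that was not tested.

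The longest run of neighbours, chosen after its values were seen, was 9 genes in 40.3 kb on sequence G at 15461373 to 15501675, with 6 on the plus and 3 on the minus strand and 8 with a single exon. It holds Nycol.G00706.v1.2 and Nycol.G00707.v1.2. Their summed level was 3403 ± 1782 TPM in outer tepals, 41.9 ± 23.3 TPM in inner tepals and 0.724 ± 0.576 TPM in stamens (SD, n = 3 each). The longest run among genes higher in stamens was 5 genes on sequence E at 23682531 to 23739649, all on the minus strand, with 127 ± 35.2 TPM in stamens, 14.6 ± 8.18 in inner tepals and 7.79 ± 5.37 in outer tepals (SD, n = 3 each). Reads shared between copies within such a run were not separable here.

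Inner tepal replicate 1 held stamen genes. Of 87 genes at 5 TPM or more in all stamens and under 1 TPM in the other 5 tepal libraries, 48 reached 1 TPM in it, which goes against a single locus. By the same rule 0 to 3 of 39 to 42 genes reached 1 TPM in any other tepal library. The sets for those libraries leave out the 48 genes, which a small share was able to lift to 1 TPM. Their low counts therefore do not show those libraries to be free of stamen material. The ratio of the 87 genes to stamen replicate 1 kept to a narrow range, with a 90th percentile 1.96 times the 25th and a median of 5.85%, and of 37 abundant stamen genes 35 lay within 2-fold of that share. This is consistent with stamen material carried into the library at about that share, at dissection or later. The remaining 5.41% of the 37 genes lay below that range, namely Nycol.B00079.v1.2 at 1.32% and Nycol.I01824.v1.2 at 0.644%, which an exact admixture of stamen replicate 1 would not give. An inner tepal close to a stamen in identity was not tested and stays open.

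Libraries with the same number deviated together, with a mean r of 0.568 across genes. Depth is argued against, since r was 0.604 among genes with a mean of at least 50 TPM, and so is a trend on transcript length or abundance, since r was 0.567 after its removal. Differences of stage or dissection along the organ axes left r at 0.574 when removed, so they are not the whole cause. Regression on the bias of reads towards a transcript end lowered r to 0.433 (0.0320 to 0.638), and since the lowest pair fell that far, this bias cannot be told apart from other causes for part of the pairs. A shared bud, plant, day or batch may lie behind the numbers, and no label says which.

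In each comparison of 6 libraries, 1 of 10 splits, the real one, gave as many genes. Fitted on those 6 libraries, the real split called 468 genes between the tepals, 4316 between stamens and outer tepals and 2558 between stamens and inner tepals, and the highest of the other splits called 0. Among the 4 splits that part all 3 pairs of numbers, the blocked fit called 2221, 5595 and 4118 in the real split and 0 at most in the others. With 10 splits no share under 0.05 can be reached. For genes higher in stamens than in both tepals, 1 of 100 splits of the 9 libraries gave 1727 or more, and the highest other gave 1645. For genes lower in stamens 1 of 100 gave 588 or more, and the highest other gave 486. Both come from the 2 drawn splits that keep the 3 stamen libraries together and remix the tepals. A further 2 set the 3 libraries of a tepal organ apart and gave at most 152 and 6, and the remaining splits gave at most 1 and 0. Because the numbers pair the libraries, 100 splits that keep 1 library of each number in each group were also drawn. Of these, 1 gave 1727 or more and 1 gave 588 or more without the block. With the block, 2 gave 2129 or more higher genes and 1 gave 998 or more lower genes, and the highest other counts, 2130 and 755, came from splits that exchange tepals and keep the stamens together. The 8 that set a tepal organ apart gave at most 405 and 40 genes, or 1093 and 247 with the block, and those that set a mixture of organs apart gave at most 1 gene in either fit. The counts closest to the real ones came only from splits that keep the 3 stamen libraries together. The counts of higher genes changed little when tepals were exchanged. Only 84 sets of 3 libraries exist, and fewer with 1 library of each number, so these splits do not exclude chance. For transcript shares, fitted on the 6 libraries of a comparison, 5, 1 and 1 of 10 splits gave as many genes as the real split, with 3, 5 and 7 genes in the real split and 5, 4 and 2 in the highest other, too few splits to reach 0.05.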
